A study of Canis lupus familiaris with 109 samples.

How the data were processed

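RNA from osteosarcoma biopsies of dogs was measured on Affymetrix Canine Genome 2.0 arrays. The deposited table holds log2 values made by RMA, per the submitters' processing notes, for 43035 probe sets, and the values run from 1.05 to 14.9 with no missing value. RMA corrects background, quantile-normalizes the arrays and summarizes probes, and its software version is not given in the sources used here. The number of arrays limits the precision of all values, and the median SE of a gene was 0.06 for long against short progression and 0.09 for the 2 drugs.

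Probe sets were named from the annotation table supplied for the series. Of the probe sets 111 were controls, 29254 had 1 gene symbol, 439 had several symbols and 13231 had none. For 27680 of those with 1 symbol the gene number was found in the RefSeq table, and 0 symbols needed an update. Each gene was represented by the probe set with the highest mean over all arrays, which gave 15115 genes, 8254 of them with more than 1 probe set. MKI67, SLFN11, CXCR4, HES1 and TP53 of the fixed gene panel were not measured under these rules. The biopsies of a tumour were averaged, since the tumour is the replicate, which gave 59 tumours.

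Tumours were grouped by the labels: progression class (short, 100 days or less; intermediate; long, over 300 days), drugs received and sex. Days, serum alkaline phosphatase, monocyte count and weight entered as log2 values and age in years. The labels carry no mark for censored times, so all recorded days were taken as observed. For each of 10 comparisons limma 3.58.1 in R 4.3.3 fitted all 59 tumours (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes at 0.05. The slope with progression by drug was tested as an interaction term with a slope for each drug class.

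Gene lists for cell types, pathways and drug response were tested with camera from limma at the preset correlation of 0.01 and with an estimated correlation, adjusted over the 27 lists with measured members. The 2 lists of X inactivation and Y chromosome genes had 0 measured members. Preset camera calls arise readily here: in 100 random orders of the tumours for long against short progression it called 7 of 27 lists on average and at least 1 in 98 of them, while the estimated correlation called 0. A list score, the mean of the members' centred log2 values, was tested by permuting tumours with 100000 resamples, or exactly for the 8 against 19 tumours of the drug comparison. These p-values were adjusted over the 27 lists of each comparison, and not over the comparisons. Genes named in each comparison are those that pass, or, where fewer than 10 pass, these and the 5 with the smallest p in each direction, plus the fixed panel for progression. Members named within a list were the ones with the smallest p or with a textbook role, picked after their values were seen.

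For the 50 tumours with 2 biopsies, the closest array was found by Pearson correlation of centred genes and tested by permuting tumour labels 100000 times. The share of variance between tumours of a gene came from duplicateCorrelation (statmod 1.5.0) over all 109 arrays. For a list score it was an intraclass correlation from the mean squares between and within the 50 pairs, with 2000 bootstrap draws for its 95% interval. Gene and list shares are thus different estimates on different samples. The consensus over genes was 0.269, and on simulated data with a share of 0.3 it was 0.319. The 4 relations of clinical and tumour values used Pearson and Spearman correlations with permutation p, adjusted over the 4.

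The tests were tested on simulated data: with tumours permuted and a change of 0.5 log2 added to 100 genes and of 1 log2 to another 100 (for slopes, over 2 SD of the measure), limma called 91% of the former in the comparison of long with short progression, 97% for the trend with progression, 74% for the drugs, and 92% each for sex and serum alkaline phosphatase. The false calls among unchanged genes numbered 12, 21, 13, 24 and 11 in these 5 comparisons. Groups, comparisons, lists, named-gene rule and most other settings were fixed before the data were examined. The settings fixed then were the tumour as a random block, a replicate block of the biopsy letter, 1 biopsy per tumour, all probe sets, a filter on low means, quantile normalization, array weights, covariates (study number, first principal component, sex, age, weight, drugs, serum level), a median split, a Cox model (survival 3.8.3) and leaving out tumours with doubtful labels. Also fixed then were ranks in place of log2 values, leaving out the tumour with the highest serum level, the other pairs of drug classes for the slope by drug, and only dogs with at least 3 treatments for the drug comparison. The permutation tests of list scores between groups and along slopes were added after seeing the data. Also chosen after seeing the data were the ratios of 3' to 5' control signal as covariates, weight alone as a covariate for list scores, leaving out each tumour in turn for the score of each list that camera called, and leaving out the 2 tumours whose sex marker goes against the label or the 1 tumour with the highest erythroid and neutrophil scores. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for list scores and permutations, and matplotlib 3.10.9 for figures. No reference genome was used.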

Results

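Bone tumour biopsies from dogs with osteosarcoma were profiled on Canine Genome arrays. The series held arrays from 59 tumours, of which 50 gave 2 biopsies and 9 gave 1, with 1 array per biopsy. The biopsies were taken at amputation, before chemotherapy with doxorubicin, carboplatin or both. By the recorded days to progression, 19 tumours fell in a short class (100 days or less, 36 arrays), 15 in an intermediate class (26 arrays) and 25 in a long class (over 300 days, 47 arrays). Median progression was 77 days in the short class, 175 in the intermediate class and 592 in the long class. Doxorubicin alone was given to 8 dogs, carboplatin alone to 19 and both drugs to 32, and 31 dogs were female and 28 male. These numbers count each tumour as 1 dog, although 2 tumours had identical labels and may come from 1 dog. Median age was 8.33 years, median weight 38.0 kg and median survival 367 days. Array medians lay between 5.75 and 5.91 on the log2 scale, and the number of arrays limits the precision of all values. Values below are log2 differences of tumour means ± SE over 59 tumours unless another error or number is given, and all tests are two-sided.

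The first question was which genes separate dogs with long and short times to progression. Values were higher in the 25 long than in the 19 short tumours, by smallest p, for ITGB7 (0.61 ± 0.14), an integrin chain of homing lymphocytes, GNB3 (0.28 ± 0.07), a G protein subunit, and KMO (0.76 ± 0.19), an enzyme of tryptophan breakdown. Next came SP100 (0.56 ± 0.14), an interferon-inducible nuclear body protein and CD226 (0.21 ± 0.05), an activating receptor of T and NK cells. ITGB7 averaged 9.08 ± 0.53 (SD) in long, 8.75 ± 0.56 in intermediate and 8.47 ± 0.23 in short tumours. KMO averaged 6.24 ± 0.79 (SD) in long and 5.47 ± 0.40 in short tumours. In the other direction stood MORN2 (-0.43 ± 0.10), GNB5 (-0.32 ± 0.08), TMLHE (-0.32 ± 0.08), an enzyme of carnitine synthesis, DTD2 (-0.24 ± 0.06) and SPRED1 (-0.27 ± 0.07), an inhibitor of Ras signalling. None of these 10 genes passed limma's test (adjusted p = 0.435 for each). With all arrays and the tumour as a random block ITGB7 passed (adjusted p = 0.0456, range 0.0456 to 0.709 over 18 alternatives). With a replicate block added ITGB7, SP100 and TMLHE passed (adjusted p = 0.0498, range 0.0498 to 0.709 for SP100 and TMLHE).

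For 4 lists of immune cells and immune activation every measured member had a higher mean in long tumours, while the B and plasma cell list was higher in 8 of 11 members (median 0.02). All 19 measured T and NK cell genes were higher, with a median difference of 0.29, among them GZMA (0.92 ± 0.29) and CCL5 (1.03 ± 0.34), a cytotoxic protease and a T cell chemokine, and CD3D (1.11 ± 0.38), a chain of the T cell receptor complex. All 16 interferon response genes were higher (median 0.31; IFI44L 0.59 ± 0.18, MX2 0.53 ± 0.17). So were all 19 macrophage genes (median 0.30; C1QA 0.43 ± 0.14, FCER1G 0.27 ± 0.09) and all 9 genes of class II antigen presentation (median 0.37; DLA-DQB1 0.57 ± 0.23, CTSS 0.30 ± 0.12). No member passed over all genes, while 8 T and NK cell, 5 interferon, 4 macrophage and 6 class II genes passed when adjusted over the list alone. The camera test with a preset correlation called the 4 lists (adjusted p = 4.37e-13, 5.81e-11, 5.81e-11 and 1.81e-06), but with an estimated correlation the adjusted p was 0.233, 0.233, 0.233 and 0.268. The mean T and NK cell score, the average of the centred members, was 0.23 ± 0.63 (SD) in long and -0.23 ± 0.29 in short tumours, and 18 of 25 long tumours lay above the short median. A permutation of the tumours, a test added after the data were seen, gave p = 0.00528 for this difference and an adjusted p of 0.0524 over 27 lists. In intermediate tumours the mean score was -0.09 for T and NK cell, -0.06 for interferon, -0.14 for macrophage and -0.14 for class II genes. In short tumours it was -0.16 for interferon, -0.12 for macrophage and -0.15 for class II genes.

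**Figure D1:**
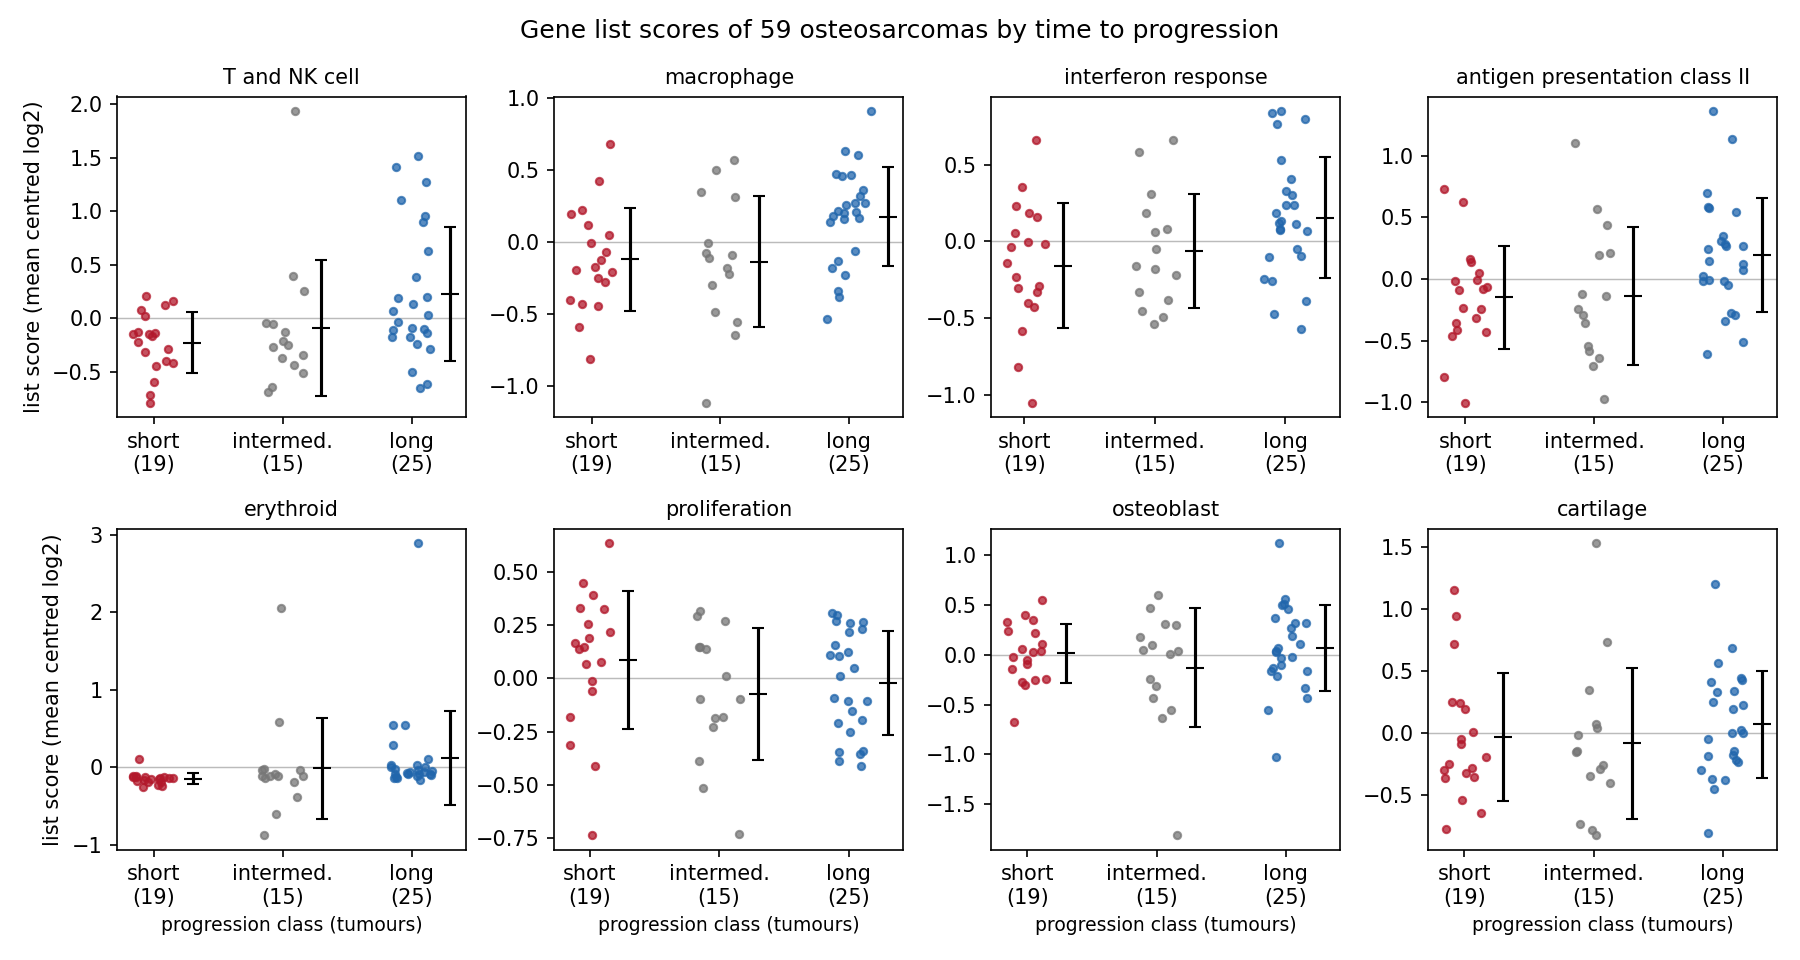
List scores (mean of the centred log2 values of a list's members, y axis) of the 59 tumours in the short (n = 19), intermediate (n = 15) and long (n = 25) classes, 1 point per tumour, with the class mean and its SD as bars. The T and NK cell score averaged -0.23 in short and 0.23 in long tumours, with an SD of 0.29 in short and 0.63 in both intermediate and long tumours.

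Other lists were called as well. The erythroid list was higher in all 11 members (HEMGN 0.61 ± 0.25, ALAS2 0.67 ± 0.34), the neutrophil list in 11 of 11 and the chemokine list in 14 of 16, with CCL4 (0.90 ± 0.28) alone passing when adjusted over the list alone. Of 17 proliferation genes 16 were lower in long tumours (median -0.09; CCNB2 -0.24 ± 0.12, BIRC5 -0.17 ± 0.09), as were 14 of 18 oxidative phosphorylation genes, and 13 of 16 fibroblast matrix genes were higher. The preset camera test gave adjusted p = 0.000506, 0.0114, 0.00124, 0.00129, 0.0271 and 0.0300 for these 6 lists in that order, and with an estimated correlation the adjusted p was 0.606, 0.606, 0.396, 0.606, 0.606 and 0.606. The neutrophil score differed by 0.38 ± 0.21 (permutation p = 0.113, adjusted p = 0.339), and by 0.21 without the 1 tumour with the highest erythroid and neutrophil scores. Leaving out the 1 tumour that moved it most took the fibroblast matrix difference from 0.11 to 0.06 and the oxidative phosphorylation difference from -0.05 to -0.03. The erythroid score differed by 0.27 ± 0.12 (permutation p = 0.00583, adjusted p = 0.0524). Without that same tumour, left out after its values were seen, the erythroid difference was 0.15 (adjusted p = 0.00864, range 0.00864 to 0.744 over 9 alternatives).

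Among the fixed panel of bone, drug and immune genes, ABCB1, the drug efflux pump, was 0.50 ± 0.21 higher in long tumours (p = 0.0230, adjusted p = 0.548). CD3E was higher by 0.25 ± 0.11 (p = 0.0283, adjusted p = 0.559) and CD163, a scavenger receptor of macrophages, 0.37 ± 0.17 (p = 0.0287, adjusted p = 0.560). The bone genes showed smaller or less certain differences: ALPL -0.21 ± 0.25, BGLAP 0.31 ± 0.29, COL1A1 0.13 ± 0.07, RUNX2 0.03 ± 0.16 and SPP1 0.09 ± 0.10. TOP2A, the target of doxorubicin, differed by 0.01 ± 0.13, ERCC1, a subunit of an excision repair nuclease, by -0.09 ± 0.05, EZR by 0.09 ± 0.06, MYC by 0.00 ± 0.12 and CXCL8 by -0.17 ± 0.31. Of 15115 genes, limma called 0, and 1180 had an unadjusted p under 0.05 (690 higher, 490 lower, 756 by chance, and 934 to 1723 over its alternatives on genes). Long and short tumours also differed in the ratio of 3' to 5' actin signal, a sign of RNA integrity (log2 ratio 0.61 ± 0.28 against 0.40 ± 0.26 SD, permutation p = 0.0123), and in the dogs' weight (median 34.7 against 47.8 kg, permutation p = 0.00015).

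A slope over all 59 tumours asked the same question without class limits. Per doubling of the days to progression, the smallest p among positive slopes belonged to SLC38A9 (0.08 ± 0.02), a lysosomal amino acid sensor, GRIA3 (0.16 ± 0.04), GNB3 (0.08 ± 0.02), SCARB2 (0.08 ± 0.02), a lysosomal membrane protein, and ZBTB4 (0.08 ± 0.02). Negative slopes with the smallest p were those of SPRED1 (-0.09 ± 0.02), GNB5 (-0.09 ± 0.02), TTC23L (-0.04 ± 0.01), MNS1 (-0.11 ± 0.03) and TMLHE (-0.08 ± 0.02). None passed, the smallest adjusted p being 0.282 for SLC38A9 and SPRED1. All 16 interferon genes had positive slopes (IFI44L 0.16 ± 0.05), as had all 19 T and NK cell genes (GZMA 0.24 ± 0.08), all 19 macrophage genes, all 9 class II genes, all 11 erythroid genes and 15 of 16 osteoblast genes. Over the list alone 8 interferon genes and 3 T and NK cell genes passed. Of 18 hypoxia genes 15 had negative slopes, and LDHA (-0.05 ± 0.02), which makes lactate, passed when adjusted over the list alone, and 13 of 17 proliferation genes were negative. The preset camera test called these 8 lists (adjusted p from 1.04e-11 for interferon to 0.0357 for proliferation). None held with an estimated correlation (adjusted p = 0.353 for all but the erythroid list, 0.623, and the proliferation list, 0.675). Leaving out the 1 tumour that moved it most toward 0 took the score slope from 0.06 to 0.04 for the osteoblast and erythroid lists. For proliferation it went from -0.0216 to -0.0141, but there the largest move was away from 0, to -0.0355 without another tumour.

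In the panel, BGLAP, which encodes osteocalcin, had a slope of 0.17 ± 0.08 per doubling of days (p = 0.0346, adjusted p = 0.696). Slopes of other panel genes were COL1A1 0.04 ± 0.02, EZR 0.04 ± 0.02, CD163 0.10 ± 0.05, ABCB1 0.11 ± 0.06, RUNX2 0.05 ± 0.04, CD3E 0.05 ± 0.03 and SPP1 0.03 ± 0.03. Slopes of ALPL (0.02 ± 0.07), TOP2A (0.01 ± 0.04), ERCC1 (-0.01 ± 0.01), MYC (0.02 ± 0.03) and CXCL8 (-0.07 ± 0.09) were within their error or close to it. Limma called 0 genes, with 1056 at an unadjusted p under 0.05 (624 positive, 432 negative, and 816 to 1741 over its alternatives on genes), and a Cox model per gene also called 0, with 1320 at an unadjusted p under 0.05. With all arrays and the tumour as a random block, SLC38A9 passed (adjusted p = 0.0226, range 0.00980 to 0.817 over 20 alternatives).

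Days of survival were also used, although they equal the days to progression in 21 tumours, so that this slope is no independent test. SLC38A9 (0.09 ± 0.02 per doubling of days), GRIA3 (0.18 ± 0.04), GNB3 (0.09 ± 0.02), TRAFD1 (0.09 ± 0.02), a brake on innate immune signalling, and ZBTB4 (0.08 ± 0.02) had the smallest p among positive slopes. Among negative ones it was MNS1 (-0.12 ± 0.03), OR6C33 (-0.06 ± 0.01), SPRED1 (-0.08 ± 0.02), ETS2 (-0.10 ± 0.03) and FAM163A (-0.03 ± 0.01). The adjusted p was 0.313 for SLC38A9 and 0.435 for TRAFD1. All 16 interferon genes, 19 T and NK cell genes, 19 macrophage genes, 9 class II genes and 11 erythroid genes had positive slopes, with 9 interferon and 7 T and NK cell genes passing when adjusted over the list alone. The interferon score had a slope of 0.10 ± 0.03 (permutation p = 0.00474, adjusted p = 0.128). By camera with the preset correlation 11 lists were called, interferon first (adjusted p = 1.59e-14), and with an estimated correlation 0, the smallest adjusted p being 0.239 for interferon. The score slope of 4 lists shrank by over 1.5 times when the 1 tumour that moved it most toward 0 was left out. These were osteoblast (0.04 to 0.03), erythroid (0.06 to 0.03), fibroblast matrix (0.0393 to 0.0248) and proliferation (-0.0226 to -0.0139). The largest move was away from 0 for fibroblast matrix (to 0.0542) and proliferation (to -0.0362), each without another tumour. Limma called 0 genes, with 1075 at an unadjusted p under 0.05 (613 positive, 462 negative).

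Because all biopsies predate treatment, the comparison of drugs asks whether the tumours that went on to different drugs differed at the start. The class may depend in part on the outcome, since some doxorubicin-only dogs with short progression received only 1 treatment. Doxorubicin-only dogs were also older than carboplatin-only dogs (median 9.64 against 7.0 years) and lighter (median 36.35 against 41.4 kg). In the 8 tumours later treated with doxorubicin only, macrophage genes had higher values than in the 19 treated with carboplatin only for 18 of 19 members, among them AIF1 (0.80 ± 0.21), CYBB (1.03 ± 0.27), a subunit of the phagocyte oxidase, LYZ (0.74 ± 0.22) and C1QB (0.88 ± 0.28). All 9 class II genes were higher, with DLA-DMB at 0.73 ± 0.24 and CD74, the invariant chain, at 0.84 ± 0.30. Over the list alone 11 macrophage and 8 class II genes passed, and over all genes 0. The macrophage score averaged 0.33 ± 0.28 (SD) against -0.16 ± 0.38 and rose by 0.48 ± 0.13 (exact permutation p = 0.00301, adjusted p = 0.0407), and 8 of 8 tumours lay above the carboplatin median. The class II score averaged 0.41 ± 0.41 (SD) against -0.16 ± 0.40 and rose by 0.57 ± 0.17 (exact permutation p = 0.00238, adjusted p = 0.0407), with 7 of 8 tumours above that median. Without the 1 tumour with the highest erythroid and neutrophil scores the differences were 0.44 and 0.55 and neither passed (exact permutation, adjusted p = 0.125 for both, range 0.0144 to 0.668 and 0.0144 to 0.616 over 9 alternatives). That tumour gave only 1 biopsy. Tumours with 1 biopsy were more frequent in the doxorubicin-only than in the carboplatin-only class, and they counted as much as the others.

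**Figure D2:**
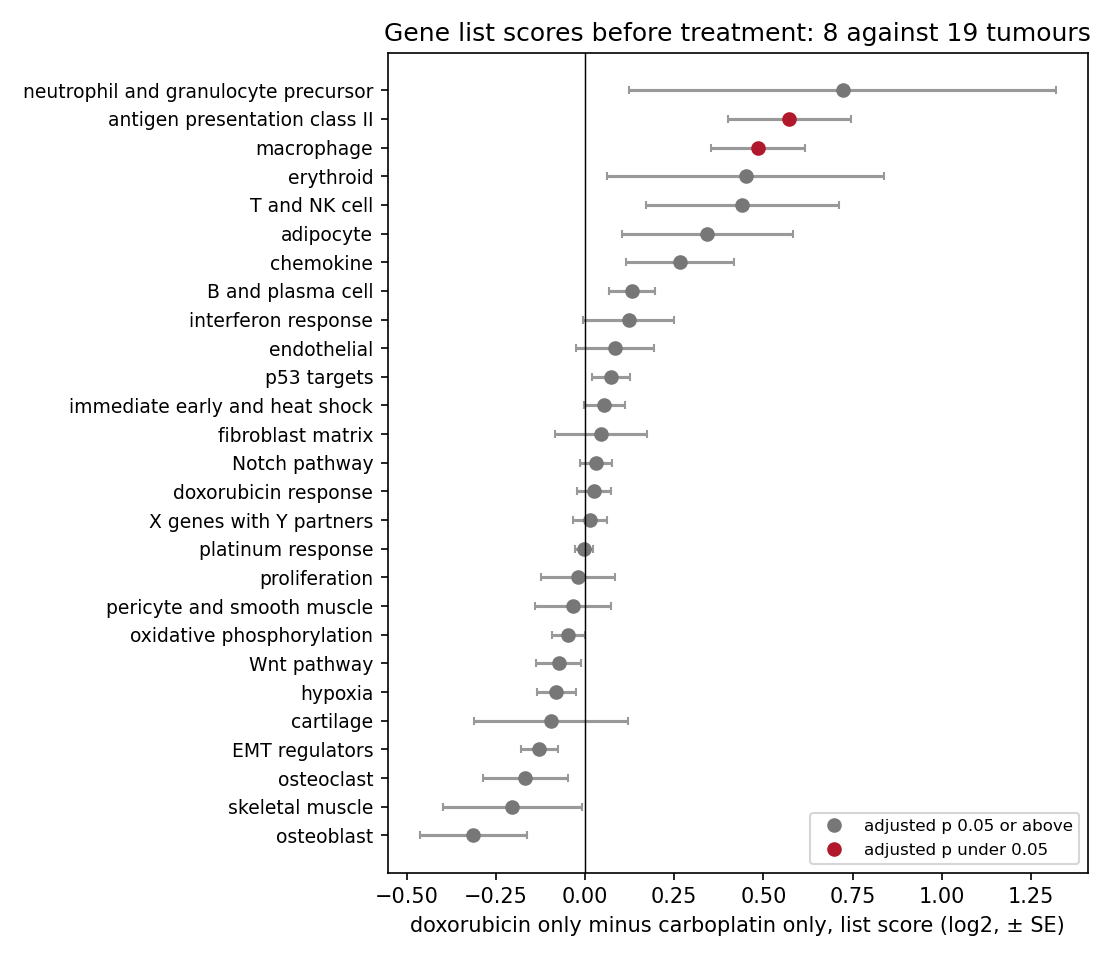
Difference in list score (mean of the centred log2 values of a list's members, x axis) between tumours later treated with doxorubicin only (n = 8) and carboplatin only (n = 19), 1 point per list, with bars for the SE. The macrophage score averaged 0.33 in doxorubicin-only and -0.16 in carboplatin-only tumours.

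Other groups went the same way or the opposite way in the doxorubicin-only tumours. All 19 T and NK cell genes, 11 erythroid genes, 11 neutrophil genes and 14 adipocyte genes were higher, with the lipase gene LIPE (0.17 ± 0.05) passing when adjusted over the list alone. The chemokine list was higher in 15 of 16 members, with CCR2 (0.16 ± 0.05), a receptor of monocytes, passing over the list alone, and the B and plasma cell list in 10 of 11. Lower were 15 of 16 osteoblast genes (ALPL -0.96 ± 0.32, OMD -0.75 ± 0.36), 13 of 15 regulators of epithelial to mesenchymal transition (EMT), 16 of 17 skeletal muscle genes and 11 of 12 osteoclast genes. ALPL, the bone alkaline phosphatase, averaged 9.95 ± 0.50 (SD) in doxorubicin-only and 10.9 ± 0.44 in carboplatin-only tumours. With the preset correlation, camera called 13 lists (adjusted p from 4.72e-13 for macrophage to 0.0468 for interferon), and with an estimated correlation 0 (adjusted p = 0.161 for macrophage, class II and EMT, and from 0.172 to 0.615 for the rest). Single tumours carried much of several of these differences. Without the tumour with the highest erythroid and neutrophil scores the erythroid difference went from 0.45 to 0.08 and the neutrophil difference from 0.72 to 0.16. Without the doxorubicin-only tumour highest for the list, T and NK cell genes went from 0.44 to 0.21, adipocyte genes from 0.34 to 0.12, chemokine genes from 0.27 to 0.14 and interferon genes from 0.12 to 0.05. Leaving out 1 tumour also took osteoclast genes from -0.17 to -0.10 and skeletal muscle genes from -0.20 to -0.09.

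The single genes with the smallest p were CCR4 (0.31 ± 0.07), a chemokine receptor of T cells, DOCK2 (0.30 ± 0.07), which drives leukocyte migration, TMEM131L (0.40 ± 0.10), MKRN1 (0.40 ± 0.10) and BEND7 (0.42 ± 0.10), all higher. Lower were PTGR2 (-0.37 ± 0.09), GPHN (-0.30 ± 0.08), ABCA5 (-0.53 ± 0.14), CEP89 (-0.42 ± 0.11) and GTPBP4 (-0.29 ± 0.08). Their limma adjusted p was 0.213, or 0.239 for GTPBP4. Limma called 0 genes, with 1258 at an unadjusted p under 0.05 (730 higher, 528 lower). That number was 740 without the tumour with the highest erythroid and neutrophil scores and 477, under the 756 of chance, with the first principal component as a covariate (smallest adjusted p 0.999).

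A gene that predicts response to 1 drug would have a slope with progression that differs between the drugs. The drug class may itself depend on the outcome, since some doxorubicin-only dogs with short progression received only 1 treatment. The largest differences of slope by p, doxorubicin only minus carboplatin only, were COLGALT2 (0.23 ± 0.06), a collagen galactosyltransferase, IGDCC4 (0.12 ± 0.03), OSR2 (0.58 ± 0.16), DEDD2 (0.15 ± 0.04) and BDNF (0.16 ± 0.05) on the positive side. On the negative side stood PRDM4 (-0.18 ± 0.05), ICAM2 (-0.26 ± 0.07) and SELE (-0.45 ± 0.14), adhesion molecules of endothelium, PARN (-0.13 ± 0.04) and GPER1 (-0.20 ± 0.06). All 11 erythroid and 11 neutrophil genes and 14 of 16 immediate early and heat shock genes had a more positive slope under doxorubicin, and all 12 osteoclast genes, 12 of 14 endothelial, 17 of 19 macrophage and 11 of 12 pericyte genes a more negative one. MYH11 (-0.51 ± 0.16), a smooth muscle myosin, passed when adjusted over the list alone. Camera with the preset correlation called 13 lists, or 8 without the tumour with the highest erythroid and neutrophil scores, and with an estimated correlation 0 (adjusted p = 0.298 for osteoclast, 0.370 for erythroid, neutrophil and endothelial). Several of these differences of slope rested on 1 tumour. Without the tumour with the highest erythroid and neutrophil scores the erythroid difference went from 0.27 to 0.00038 and the neutrophil difference from 0.39 to -0.02. Leaving out the 1 tumour that moved it most toward 0 or past it took adipocyte genes from -0.18 to -0.0044 and skeletal muscle from -0.12 to 0.01. In the same way macrophage went from -0.12 to -0.07, fibroblast matrix from -0.11 to -0.06 and oxidative phosphorylation from -0.04 to -0.02. Interferon went from -0.08 to -0.04 and class II from -0.10 to -0.06, but for both the largest move was away from 0, to -0.17 without another tumour. Limma called 0 genes, with a smallest adjusted p of 1.00 and 470 at an unadjusted p under 0.05 (275 positive, 195 negative), and with array quality weights it called 63, with 1414 at an unadjusted p under 0.05.

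Sex was compared because its genes also check the labels. EIF2S3, an X-linked translation factor with a Y partner, fell by 0.28 ± 0.05 from 12.04 ± 0.19 (SD) in 31 females to 11.76 ± 0.19 in 28 males (limma adjusted p = 0.00495), and 26 of 28 males lay below the female median. The list of X genes with Y partners fell as a group: 10 of 12 members were lower in males, 1 passing over all genes and 6 when adjusted over the list alone. Among these were KDM6A (-0.42 ± 0.09, adjusted p = 0.134), a histone demethylase, TXLNG (-0.18 ± 0.04, adjusted p = 0.139) and DDX3X (-0.13 ± 0.03, adjusted p = 0.519), an RNA helicase. TRAPPC2, which is not in the list, was lower as well (-0.29 ± 0.07, adjusted p = 0.460). These 4 genes passed with all arrays and the tumour as a random block (adjusted p = 0.00154, 0.0177, 0.0108 and 0.0177 in that order). Over 15 alternatives their adjusted p ranged from 0.00154 to 0.707, from 0.0130 to 0.707, from 0.000145 to 0.844 and from 0.0168 to 0.814. The list score fell by 0.12 ± 0.03 (permutation p = 2e-05, adjusted p = 0.00054), and camera gave adjusted p = 1.04e-10, or adjusted p = 8.42e-05 with an estimated correlation. A second probe set annotated to EIF2S3, which does not stand for the gene because its mean is lower, rose by 3.22 in males, to 8.20 ± 1.00 (SD) from 4.98 ± 0.97 in females (limma over all probe sets, adjusted p = 4.93e-14).

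**Figure D3:**
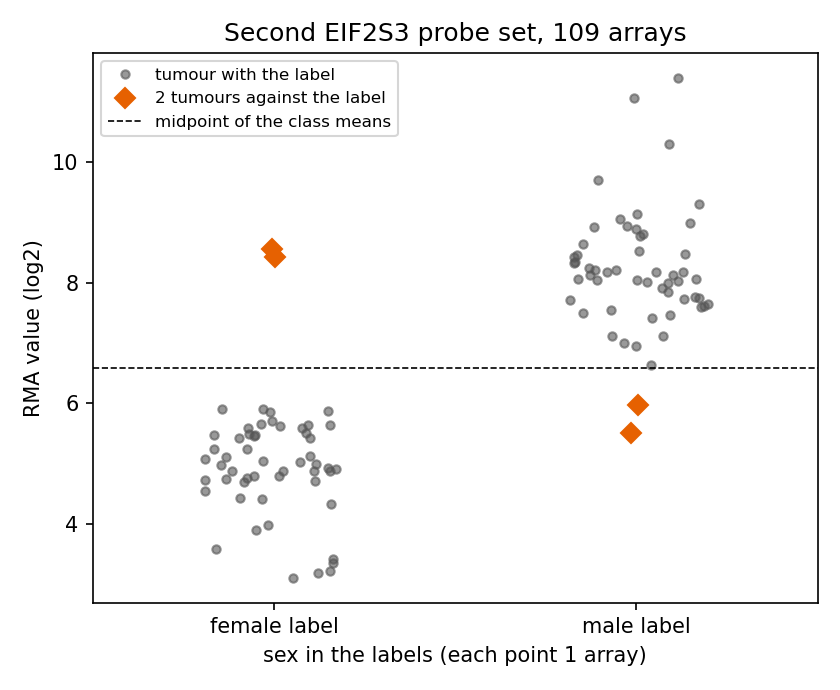
Log2 signal of the second probe set annotated to EIF2S3 (y axis), 1 point per array. The arrays come from tumours labelled female (n = 31) and male (n = 28), and arrays of the same tumour are not independent. Over tumours, males averaged 8.20 and females 4.98, and 1 tumour of each label lay on the other side of 6.59, the midpoint of the class means.

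Hypoxia genes had higher values in males on average over tumours. Of 18 members 14 were higher, and 5 passed when adjusted over the list alone against 0 over all genes. CA9 (0.43 ± 0.13), a carbonic anhydrase induced by low oxygen, ADM (0.48 ± 0.15), EGLN3 (0.43 ± 0.14), an oxygen sensor, and SLC2A1 (0.26 ± 0.09), a glucose transporter, were among them. The hypoxia score was 0.07 ± 0.13 (SD) in males and -0.06 ± 0.17 in females, a rise of 0.14 ± 0.04 (permutation p = 0.00125, adjusted p = 0.0169), with 24 of 28 males above the female median. Camera gave adjusted p = 2.90e-06, or adjusted p = 0.0437 with an estimated correlation. With only the last biopsy of each tumour the difference was 0.11 and did not pass (adjusted p = 0.986, range 0.0223 to 0.986 over 9 alternatives).

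A further 6 lists were called by camera with the preset correlation alone. All 16 osteoblast and 11 erythroid genes were lower in males, as were 11 of 11 neutrophil and 12 of 14 endothelial genes, and 15 of 17 proliferation and 16 of 17 skeletal muscle genes were higher. Their adjusted p was 0.00013, 0.000744, 0.0294, 0.00493, 0.00341 and 0.0276, and with an estimated correlation 0.654 for osteoblast and 0.868 for the other 5. Without the tumour with the highest erythroid and neutrophil scores the neutrophil difference went from -0.20 to -0.06 and the erythroid difference from -0.18 to -0.09, and without the male highest for skeletal muscle genes that difference went from 0.13 to 0.05. CHIC2 (0.23 ± 0.06, adjusted p = 0.650), NEFH (0.42 ± 0.12), CLOCK (0.20 ± 0.06), TEAD4 (0.23 ± 0.07) and CA9 had the smallest p among genes higher in males and did not pass. In all, limma called 1 gene, with 641 at an unadjusted p under 0.05 (419 higher in males, 222 lower). Males were heavier (median 41.3 against 34.6 kg), and with age and weight as covariates 2212 genes had an unadjusted p under 0.05 and limma called 1.

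Serum alkaline phosphatase, a marker of bone formation used in prognosis, was set against tumour expression. Per doubling of the serum level, all 16 interferon genes had negative slopes and all 11 neutrophil genes positive ones, and 6 neutrophil genes passed when adjusted over the list alone, including the granule proteins S100A9 (0.44 ± 0.16), LTF (0.47 ± 0.18) and CAMP (0.36 ± 0.14). Slopes were negative for 13 of 16 osteoblast genes, with COL1A1 (-0.07 ± 0.02) and RUNX2 (-0.16 ± 0.06) passing over the list alone, for all 12 osteoclast genes and for 13 of 15 EMT regulators, with SNAI2 (-0.12 ± 0.03) and EZR (-0.08 ± 0.02) passing over the list alone. For this slope the preset camera test called 9 lists (adjusted p = 1.12e-09 for interferon and 1.40e-08 for neutrophil), and with an estimated correlation 0 (adjusted p = 0.333 for both, 0.345 for osteoblast and osteoclast, 0.107 for EMT). Leaving out the 1 tumour that moved it most took the score slope from 0.25 to 0.15 for neutrophil, from -0.07 to -0.02 for osteoblast, from -0.06 to -0.02 for T and NK cell, from 0.08 to 0.02 for erythroid and from 0.07 to -0.06 for skeletal muscle genes. The single genes with the smallest p were ABRA (0.09 ± 0.02), NIPAL1 (0.12 ± 0.03), SLC22A3 (0.12 ± 0.03), JPH1 (0.09 ± 0.02) and METTL21C (0.10 ± 0.02) upward. Downward they were FTH1 (-0.12 ± 0.03), the ferritin heavy chain, CUX1 (-0.06 ± 0.01), SNAI2, EZR and CRY1 (-0.09 ± 0.02). None passed (smallest adjusted p 0.373), and limma called 0 genes with 1008 at an unadjusted p under 0.05 (505 positive, 503 negative, and 665 to 1460 over its alternatives on genes).

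Between clinical and tumour values 4 relations were tested in 59 tumours. Serum alkaline phosphatase and tumour ALPL had r = -0.167 (permutation p = 0.200, adjusted p = 0.400) and rho = -0.133 (permutation p = 0.318), and r = -0.362 without the 2 farthest tumours (permutation p = 0.00538, adjusted p = 0.0215), a step whose p was computed only after r was seen. The osteoblast score gave r = -0.179 (permutation p = 0.170, adjusted p = 0.400) and rho = -0.103 (permutation p = 0.437), and r = -0.296 without the 2 farthest (permutation p = 0.0258, adjusted p = 0.0516). Blood monocytes and the macrophage score gave r = 0.0447 (permutation p = 0.736, adjusted p = 0.736) and rho = 0.0658 (permutation p = 0.620), and r = 0.0392 without 2. Body weight and the adipocyte score gave r = -0.102 (permutation p = 0.435, adjusted p = 0.580) and rho = -0.0831 (permutation p = 0.529), and r = 0.0274 without 2. None of the 4 relations passed in all 59 tumours, and the first passed only without the 2 farthest. With the first biopsy alone r was -0.264 for ALPL (permutation p = 0.0461, adjusted p = 0.0922), -0.283 for the osteoblast score (permutation p = 0.0315, adjusted p = 0.0922), 0.167 for monocytes (permutation p = 0.206, adjusted p = 0.275) and 0.0377 for weight (permutation p = 0.776, adjusted p = 0.776).

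With blood monocyte counts, all 18 oxidative phosphorylation genes had positive slopes per doubling (COX5B 0.08 ± 0.03, NDUFV1 0.08 ± 0.03), and 11 of 14 endothelial genes negative ones, EMCN (-0.22 ± 0.07), an endothelial sialomucin, passing when adjusted over the list alone. Of 12 pericyte genes 11 were negative, of 12 osteoclast genes 11, and 17 of 19 T and NK cell and 9 of 11 B and plasma cell genes were positive. These 6 lists were called by camera with the preset correlation (adjusted p = 7.08e-08 for oxidative phosphorylation), and with an estimated correlation 0 (adjusted p = 0.196 for oxidative phosphorylation, 0.466 for endothelial and pericyte). Leaving out the 1 tumour that moved it most toward 0 took the score slope from 0.05 to 0.03 for oxidative phosphorylation and from -0.09 to -0.04 for pericyte genes. It went from 0.10 to 0.04 for T and NK cell and from -0.05 to -0.03 for osteoclast genes. For osteoclast genes the largest move was away from 0, to -0.0746 without another tumour. Top single genes were PHF5A (0.11 ± 0.03), GLOD4 (0.12 ± 0.03), C20H19orf53 (0.13 ± 0.04), HOOK2 (0.14 ± 0.04) and ERAL1 (0.08 ± 0.03) upward. Downward they were EGFL8 (-0.12 ± 0.03), WDFY1 (-0.07 ± 0.02), FAM199X (-0.07 ± 0.02), COL4A1 (-0.19 ± 0.05), a basement membrane collagen, and INKA1 (-0.18 ± 0.05). None passed (adjusted p = 1.00), and limma called 0 genes with 526 at an unadjusted p under 0.05 (247 positive, 279 negative, and 366 to 1198 over its alternatives on genes).

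Cartilage genes fell with the dog's age. Of 15 members 12 had negative slopes, 5 passing when adjusted over the list alone and 0 over all genes, among them ACAN (-0.18 ± 0.04 per year), the main cartilage proteoglycan, HAPLN1 (-0.19 ± 0.05), its link protein, COL11A2 (-0.09 ± 0.02) and COL9A1 (-0.11 ± 0.04). The cartilage score fell by 0.08 ± 0.02 per year (permutation p = 0.00188, adjusted p = 0.0467), and 22 of 29 dogs over the median age lay below the median of the 30 others. Camera gave adjusted p = 1.45e-09, or adjusted p = 0.0224 with an estimated correlation. With log2 body weight as a covariate the slope was -0.07 and did not pass (adjusted p = 0.132, range 0.0251 to 0.333 over 9 alternatives). The platinum response score, of repair and transport genes, fell by 0.01 ± 0.00 per year (permutation p = 0.00346, adjusted p = 0.0467). It did not pass without the tumour with the highest erythroid and neutrophil scores (adjusted p = 0.0589, range 0.0358 to 0.958 over 9 alternatives), and camera gave adjusted p = 0.0252, or adjusted p = 0.165 with an estimated correlation.

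All 17 proliferation genes had negative slopes with age, as had 14 of 16 fibroblast matrix genes, with OGN (-0.09 ± 0.03), COL12A1 (-0.09 ± 0.03) and ASPN (-0.14 ± 0.05) passing when adjusted over the list alone, 14 of 16 osteoblast and 10 of 12 pericyte genes. Of the 11 neutrophil and 11 erythroid genes 10 each were positive. These lists were called by camera with the preset correlation alone, and with an estimated correlation the adjusted p was 0.631 for the first 4 and 0.726 for the last 2. Without the tumour with the highest erythroid and neutrophil scores the preset test called 5 lists instead of 8, and the score slope went from 0.06 to 0.03 for neutrophil and from 0.0270 to 0.0109 for erythroid genes. Leaving out 1 other tumour, the one that moved each most, took it from -0.0239 to -0.0130 for osteoblast, from -0.0208 to -0.0127 for pericyte and from -0.0337 to -0.0178 for fibroblast matrix genes. RILP (0.03 ± 0.01), DUSP23 (0.07 ± 0.02), NAPRT (0.07 ± 0.02), an enzyme of NAD synthesis, DENND2A (0.03 ± 0.01) and SPRY1 (0.06 ± 0.02) had the smallest p upward. Downward it was CC2D2B (-0.05 ± 0.01), ACAN, DIAPH3 (-0.06 ± 0.02), ZC3H13 (-0.07 ± 0.02) and PDZRN4 (-0.11 ± 0.03). None passed (smallest adjusted p 0.541), and limma called 0 genes with 717 at an unadjusted p under 0.05 (351 positive, 366 negative, and 546 to 1798 over its alternatives on genes).

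Body weight gave the largest number of small p-values of the 10 comparisons. Per doubling of weight, DIAPH3 (0.38 ± 0.09) and UBE2C (0.14 ± 0.03), which act in cell division, IHH (0.14 ± 0.03), a signal of growing cartilage, ITGB1BP2 (0.37 ± 0.09) and HOXB1 (0.10 ± 0.02) had higher values. Lower values with weight belonged to APOBEC3Z3 (-0.51 ± 0.11), an antiviral deaminase, SSBP4 (-0.24 ± 0.05), SMARCA2 (-0.26 ± 0.06), a chromatin remodeller, SYNE1 (-0.33 ± 0.07) and FAM149A (-0.69 ± 0.16). Their adjusted p was 0.132, or 0.138 for IHH, DIAPH3 and UBE2C. Limma called 0 genes with 1717 at an unadjusted p under 0.05 (911 positive, 806 negative), and with sex and age as covariates 2, with 3047 at an unadjusted p under 0.05. With all arrays and the tumour as a random block it called 55 genes, and APOBEC3Z3 reached its smallest adjusted p with array quality weights (0.00457, range 0.00457 to 0.378 over 15 alternatives). All 17 proliferation genes and 12 of 15 cartilage genes had positive slopes, and 15 of 16 interferon, 17 of 19 T and NK cell, 17 of 19 macrophage, 8 of 9 class II and 13 of 16 chemokine genes negative ones. Camera with the preset correlation called these 7 lists (adjusted p = 1.12e-07 for interferon), and with an estimated correlation the adjusted p was 0.669 for each. Leaving out the 1 tumour that moved it most took the score slope from -0.16 to -0.08 for macrophage, from -0.22 to -0.11 for T and NK cell, from 0.15 to 0.09 for proliferation, from -0.27 to -0.17 for interferon, from -0.22 to -0.12 for class II and from -0.12 to -0.06 for chemokine genes.

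The 2 biopsies of a tumour were compared to see how much of the variation lies between tumours. Of 100 biopsies with a partner, 46 had that partner as their closest array by correlation of centred values, against 0.925 on average and 11 at most in permutations (permutation p = 1e-05, the smallest that 100000 permutations can give). In 21 tumours each biopsy was closest to the other, and in 25 neither was. The median correlation of partners across genes was 0.199, with a range of -0.394 to 0.836, against -0.0136 for biopsies of different tumours, and genes are not independent replicates. The share of variance between tumours (intraclass correlation) was 0.315 for the median gene, and 4169 genes (27.6%) were above 0.5. Named genes with a high share included GPR158 (0.944), PLAA (0.926), MRPL21 (0.910), ERAS (0.906), MFAP3 (0.899), CAMP (0.896), a neutrophil granule peptide, and HK3 (0.895), the hexokinase of myeloid cells.

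Lists differed in how alike the 2 biopsies of a tumour were. The share between tumours was highest for p53 targets (0.717, 95% interval 0.500 to 0.845), X genes with Y partners (0.683), neutrophil genes (0.676), T and NK cell genes (0.625, interval 0.391 to 0.753), oxidative phosphorylation (0.601) and osteoblast genes (0.552). Chemokine (0.485), osteoclast (0.459), fibroblast matrix (0.430), class II (0.424) and macrophage genes (0.396) lay between. Interferon (0.281), Wnt pathway (0.279), adipocyte (0.269), platinum response (0.263), and endothelial genes (0.206, permutation p = 0.0441, adjusted p = 0.0541 over 27 lists) were lower. No share between tumours was detectable by unadjusted permutation p for doxorubicin response (0.230, permutation p = 0.0515), pericyte (0.187, permutation p = 0.0785), B and plasma cell (0.159, permutation p = 0.144), hypoxia (0.0593, permutation p = 0.323) and skeletal muscle genes (-0.0597, permutation p = 0.778).

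**Figure D4:**
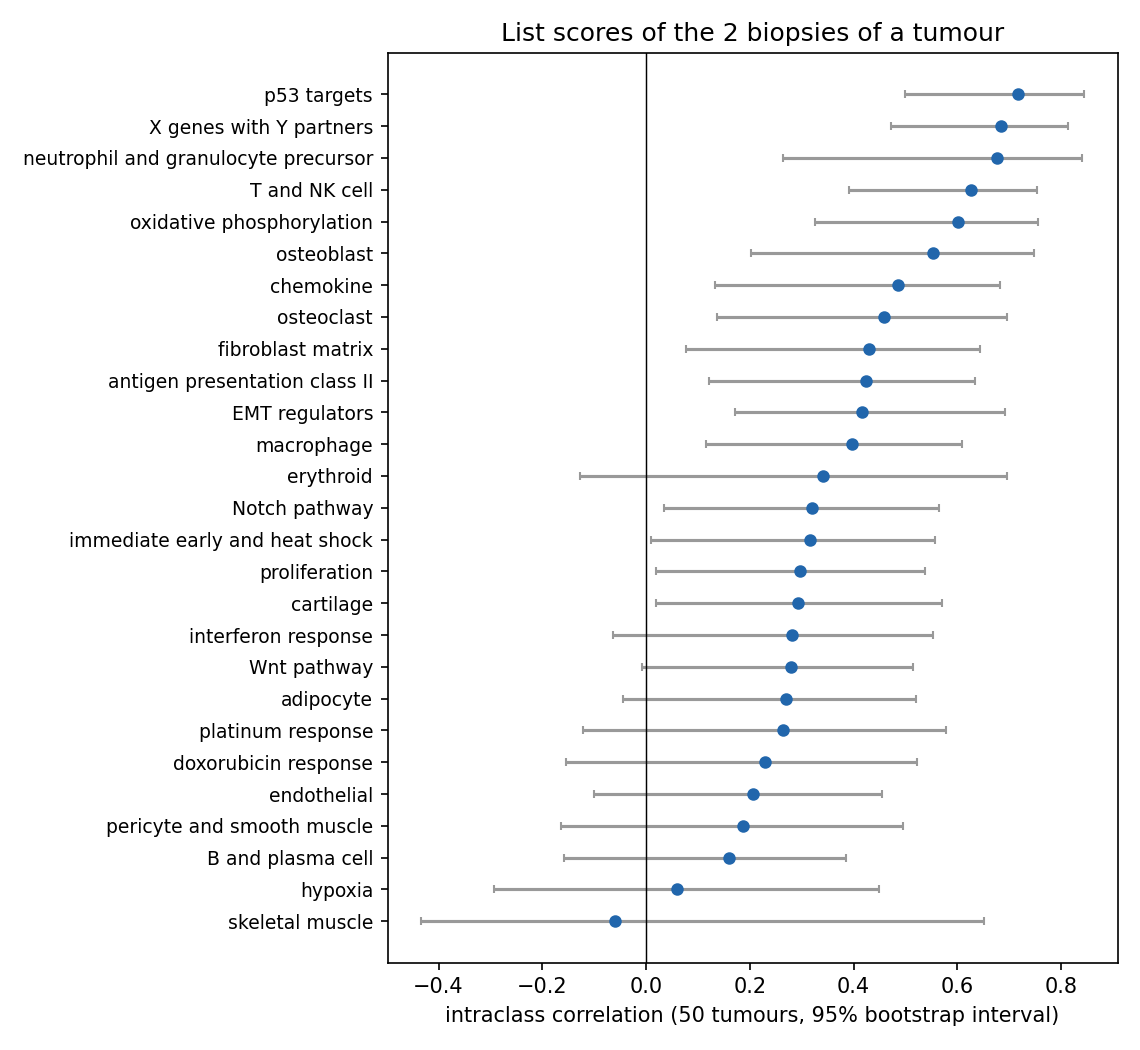
Intraclass correlation of each list score (x axis, no unit) in the 50 tumours with 2 biopsies, 1 point per list, with bars for the 95% bootstrap interval. P53 targets stand at 0.717 and T and NK cell genes at 0.625, while hypoxia (0.0593) and skeletal muscle (-0.0597) lie near 0.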

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

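In this part the tests of body weight and tumour cell share, of the sex marker, and of mislabelled biopsies were chosen only after the result was seen, as were the 3' to 5' ratios as a setting. What RNA quality, and tissue mixture in the pairs, would show was written down before those tests were run.

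The mean of the macrophage, T and NK cell, interferon and class II scores, a set chosen because these 4 lists differed, was 0.352 ± 0.104 higher in long than in short tumours (permutation p = 0.00148). RNA quality as the whole cause is argued against, since the difference stayed at 0.345 with the 3' to 5' ratios as covariates (permutation p = 0.00255). The classes differed in weight, but with log2 weight as a covariate the difference was 0.323 (permutation p = 0.0110), which argues against weight as the whole cause. A lower share of tumour cells could raise all other cell types alike, but the 4 immune lists differed by 0.748 ± 0.221 standard deviations and 5 stromal lists by 0.158 ± 0.185, a gap of 0.590 ± 0.268 (permutation p = 0.0305) that was 0.533 ± 0.316 with weight (permutation p = 0.0937), 0.477 ± 0.255 with the 3' to 5' ratios (permutation p = 0.0612) and 0.493 ± 0.324 with sex, age and weight as covariates (permutation p = 0.122). Because the 4 lists were chosen for their size and the gap with covariates is within 2 SE, tumour cell share and a change of immune cells cannot be told apart, and both stay open as hypotheses found and tested on the same data.

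A second probe set annotated to EIF2S3, left out of the comparisons of genes and tested only among all probe sets, was 3.22 log2 higher in males than in females, and by this signal 2 tumours went against their label. The tumour labelled female stood at 8.49, with biopsies at 8.56 and 8.43, and the tumour labelled male at 5.73, with biopsies at 5.96 and 5.51, on either side of the midpoint of 6.59. An exchanged or wrong sex label could give this, yet the X gene score of the tumour labelled male was -0.0324, on the male side of the midpoint of -0.0013 and close to it, while that of the tumour labelled female was -0.09, so no value decides for the 2 together. Gain or loss of signal within the tumour could give it as well, and the largest difference between the 2 biopsies of such a tumour, 0.456, lay within the 0.910 reached in the other 48 pairs. These explanations cannot be told apart with 2 tumours, and no biological explanation beyond them was tested.

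Only 46 of 100 biopsies were closest to their partner. Mislabelled biopsies are argued against by DLA88, a class I histocompatibility gene, whose probe set with 2 separate levels gave both biopsies the same level in 29 of 29 pairs not closest to each other (100%), against 50.6% in random pairs. This probe set was chosen after its values were seen, since a first rule with 10 probe sets gave 257 of 290 comparisons alike (88.6%) against 85.2% in random pairs, too close to decide. With 13 cell type scores regressed out 40 biopsies were closest to their partner, no more than before. This cannot decide on tissue mixture, because the step also removes what partners share in these scores. Their share between tumours ran from -0.0597 for skeletal muscle to 0.676 for neutrophil genes. With the 3' to 5' ratios regressed out 43 were closest to their partner. How far partners share these ratios was not tested, so RNA quality is not decided either. The differences within tumours may be regional, which is a hypothesis that was not tested.

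In the 8 tumours treated with doxorubicin only, 37 values were examined for a tumour far from the others, as the gap to the next tumour over the whole range, and 11 stood out, where chance gives about 1 in 20. The highest tumour stood apart for MKRN1 (0.708) and BEND7 (0.634). So did the highest for the cartilage (0.603), T and NK cell (0.606), neutrophil (0.688), erythroid (0.746), skeletal muscle (0.575), adipocyte (0.687), chemokine (0.711) and Notch pathway (0.644) scores, the highest tumour not being the same in each. The lowest tumour stood apart for the doxorubicin response score (0.697). The tumour with the highest erythroid and neutrophil scores, which gave only 1 biopsy, accounted for 4 of the 11.

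For 13 lists the slope with progression differed between doxorubicin only and carboplatin only by camera on the interaction term with the preset correlation, and for none with an estimated one. Without the tumour with the highest erythroid and neutrophil scores the preset test called 8 lists, and the erythroid difference went from 0.27 to 0.00038. The slope was more positive under doxorubicin for erythroid (adjusted p = 2.02e-08), neutrophil (2.77e-06) and immediate early and heat shock genes (0.00718). It was more negative for osteoclast (2.02e-08), endothelial (0.00018), macrophage (0.000223), adipocyte (0.000288), oxidative phosphorylation (0.00193), pericyte (0.00613), fibroblast matrix (0.00718), skeletal muscle (0.0202), interferon (0.0223) and class II genes (0.0311).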

How the results depend on the processing

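The alternatives with 3' to 5' ratios, with weight alone, without the 2 tumours against their sex label, without each tumour in turn and without the tumour with the highest erythroid and neutrophil scores were chosen only after the results were seen. None of the settings fixed beforehand was left out. Of 166 recomputed counts of called genes 145 stayed within 1.5 times the count. Of 2126 recomputations of 126 results for named genes 2036 kept their direction and side of the threshold. A further 43 newly passed, 0 were lost and 47 turned. These tallies say little about stability. The fit on tumour means called 0 genes in every comparison but sex, and EIF2S3 was the only named result that passed. No other result could be lost, and most of those that kept their side passed in neither fit. EIF2S3 passed in every alternative for sex (adjusted p from 1.3e-06 to 0.0415). The biopsy letters do not pair the samples, since arrays of different classes that share a letter correlated at -0.0014 on average and those with different letters at 0.0004. The number of tumours limits the precision of small differences, and the turned values are mostly near 0. For the values below the cause was not tested. The block fits use all arrays, but the independent samples remain the 59 tumours. They apply 1 within-tumour correlation to every gene, such as 0.267 for long against short progression. The share between tumours was 0.315 for the median gene and above 0.5 for 27.6% of genes. For genes with a higher share than the one applied, p in the block fits may be too small.

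With the tumour as a random block limma called 1 gene for long against short progression (ITGB7), 1 for the trend with progression (SLC38A9), 6 for sex, 1 for serum alkaline phosphatase (ABL1), 2 for age (NRN1, TNIK) and 55 for weight. With the replicate block it called 3 for long against short (ITGB7, SP100, TMLHE), 1 for the trend and 1 for survival (SLC38A9 in both), 6 for sex, 2 for age (NRN1, TNIK) and 49 for weight, and compared with the fit on tumour means the replicate block changed no other count. It called 0 for serum alkaline phosphatase, where ABL1 did not pass. Array weights gave 1 for the trend and 1 for survival (ZNF214 in both), 63 for the slope by drug, 6 for sex, 1 for age (ARAP1) and 45 for weight. The 6 for sex were DDX3X, EIF2S3, KDM6A, OFD1, TRAPPC2 and TXLNG in all 3 fits. All probe sets gave 7 probe sets for sex and 1 for weight. Sex and age as covariates gave 2 genes for weight (FAM83B, OR11M1P). Genes outside the naming rule were named here after their values were seen.

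Lists called with an estimated correlation numbered 0 for long against short, 0 for the trend, 0 for survival, 0 for the drugs, 0 for the slope by drug, 2 for sex, 0 for serum alkaline phosphatase, 0 for monocytes, 1 for age and 0 for weight. By permutation of scores, a test added after the data were seen, they numbered 0, 0, 0 and 2 for long against short, trend, survival and drugs. For sex, serum alkaline phosphatase, monocytes, age and weight they numbered 2, 0, 0, 2 and 0. No adjustment was made over the comparisons, so chance is not excluded for the drug, hypoxia and age lists that passed. With the first principal component as a covariate camera called 6 for long against short, 6 for survival and 4 for weight. Without the tumour with the highest erythroid and neutrophil scores it called 8 for the slope by drug and 5 for age.

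Turned values for long against short (log2) were as follows. ALPL was 0.0973 with the first principal component and 0.0013 with a median split. RUNX2 was -0.0235 with the first biopsy, -0.0075 with array weights, -0.0230 with study number, -0.0036 with a median split and -0.0794 with the 3' to 5' ratios. SPP1 was -0.0150 with the ratios and EZR -0.0064 with array weights. TOP2A was -0.0235 with the random block, -0.0180 with the replicate block, -0.0666 with the first biopsy, -0.0036 with quantile normalization, -0.0745 with array weights, -0.0196 with study number and -0.0410 with the ratios. MYC was -0.0045 with the random block, -0.0105 with the replicate block, -0.0135 with the first biopsy, -0.0098 with quantile normalization, -0.0237 with array weights, -0.0109 with study number, -0.0197 with sex, age and weight, -0.0208 with a median split, -0.0020 without the tumour whose progression exceeds survival and -0.0083 without the tumour with the highest erythroid and neutrophil scores. CXCL8 was 0.0707 with the last biopsy and 0.2425 with sex, age and weight.

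For the trend with progression, ALPL was -0.0067 with the last biopsy, -0.0357 with array weights, -0.0049 with drugs, -0.0080 without the tumour whose progression exceeds survival, -0.0033 with serum alkaline phosphatase and -0.0303 with the ratios. TOP2A was -0.00027 with the random block, -0.0177 with the first biopsy, -0.0274 with array weights, -0.0083 with study number, -0.0054 with serum alkaline phosphatase and -0.0035 with the ratios. SPP1 was -8.6e-05 and ERCC1 0.0099 with the ratios, ERCC1 0.0024 with the first biopsy and 0.401 in the Cox model (the negative of the log hazard per log2 unit), and CXCL8 0.0278 with sex, age and weight. PRDM4 was 0.0195 for both drugs against carboplatin only, METTL21C -0.0139 for serum alkaline phosphatase with the last biopsy, and the correlation of weight with the adipocyte score 0.0377 with the first biopsy. With 1 tumour left out, among the scores of lists called by camera, the slope of the skeletal muscle score with serum alkaline phosphatase turned to -0.0645, and for the slope by drug the neutrophil score turned to -0.0155 and the skeletal muscle score to 0.0114. None of the others turned.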

Other observations

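The DLA88 probe set, the permutation-based comparison of B and plasma cell and drug response scores, and the values of the tumour with the highest erythroid score were chosen only after the results were seen, and the counts over random orders of the tumours were planned. DLA88, which encodes the main canine class I molecule, showed 2 separate levels with a gap of 1.61 log2, 60 arrays lying above it. Both biopsies stood at the same level in 50 of 50 tumours, where random pairs gave 25.2 on average. The largest shares of variance between tumours belonged to LOC478000 (0.960) and LOC100856727 (0.952), and CATSPERD (-0.936), GCM2 (-0.935) and VSTM1 (-0.795) had the lowest among the third of genes with the largest variance.

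Scores of 2 smaller lists were also higher in long than in short tumours without passing: doxorubicin response by 0.07 ± 0.03 (permutation p = 0.0169, adjusted p = 0.0650) and B and plasma cells by 0.08 ± 0.03 (permutation p = 0.0204, adjusted p = 0.0689). The tumour with the highest erythroid score stood at 2.89, with the next at 2.06, and its neutrophil score of 4.30 was above the next at 3.75. The EMT score had a slope of -0.04 ± 0.01 per doubling of serum alkaline phosphatase (permutation p = 0.00573, adjusted p = 0.155), and the oxidative phosphorylation score 0.05 ± 0.02 per doubling of monocytes (permutation p = 0.0097, adjusted p = 0.262). The weight slope of the interferon score was -0.27 ± 0.12 (permutation p = 0.0259, adjusted p = 0.406).

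The tumours were put in 100 orders, the real one included, and each count was compared with the others. For genes at an unadjusted p under 0.05, weight alone was reached in under 5 of 100 orders (1717, 4 orders, highest other 2364). This is under the limit of 5 orders for a single count, but it does not exclude chance, since weight is the best of 10 comparisons. Chance cannot be excluded for long against short (1180, 8 orders, highest other 2272), the trend (1056, 22, 2191), survival (1075, 18, 2153), drugs (1258, 15, 2111) and slope by drug (470, 71, 4639). The same held for sex (641, 57, 2420), serum alkaline phosphatase (1008, 23, 2365), monocytes (526, 63, 2001) and age (717, 50, 2863). Of the called genes only sex had any, and its count of 1 was reached in 4 orders (highest other 12). This too is under the limit for a single count but does not exclude chance for 1 of 10 comparisons. For lists called by camera with the preset correlation chance cannot be excluded in any comparison: long against short (10 lists, 24 orders, highest other 13), trend (8, 44, 14), survival (11, 12, 17), drugs (13, 6, 14) and slope by drug (13, 5, 15). In the same order, lists called, orders and highest other were sex (8, 47, 14), serum alkaline phosphatase (9, 22, 14), monocytes (6, 62, 16), age (8, 40, 13) and weight (7, 39, 15). Some random orders gave several times the real count, such as 4639 genes for the slope by drug, which may reflect a structure of the samples or correlation between genes, and the cause was not tested.

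In the labels 21 tumours had equal days of progression and survival, 1 had more days of progression than of survival, and 2 had identical labels in every characteristic.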
